A study of Homo sapiens with 4 samples.

How the data were processed

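RNA was sequenced from cells labelled MDA-MB-231, an established human breast cancer line of mesenchymal, triple-negative type. The 4 libraries fall into 2 groups by their titles: 2 libraries of cells exposed to HET0016 (5 µM for 48 h) and 2 libraries titled NC, taken here as cells without HET0016. HET0016 is a small-molecule inhibitor of the CYP4A and CYP4F omega-hydroxylases that form 20-HETE from arachidonic acid. The labels give 2 libraries per group in one place and speak of triplicates in another, and the text describing the exposure is repeated on the NC samples; the groups therefore rest on the titles. No label says whether replicates came from separate cultures, so p-values rest on the spread between these libraries, which may be technical. The main test took that spread mostly from genes of like expression. IGFBP6 (SD 604 in NC and 227 with HET0016) and AMOTL2 (10.2 and 34.8) thus both had an SE of 0.093. Very small p-values therefore do not measure the spread of the named gene itself, which 2 libraries per group estimate poorly.

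Libraries were made with the Illumina TruSeq RNA Sample Prep Kit, which selects polyadenylated RNA and does not mark strand, and were sequenced on the Illumina GAIIx, per the labels' protocols. The submitters' processing notes name Bowtie 0.12.2 and the genome builds hg38 and hg18 without their roles. The read counter, its strand setting and the annotation are not given in the sources used here. Each file lists 27283 genes, and coordinates of 100% of them match GENCODE release 29 (Ensembl release 94, GRCh38), so positions below are on GRCh38.

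The deposited values are a normalised signal per gene: read counts that the authors divided by one size factor per library, as read from the values themselves. Within a library every value was a whole multiple of one step, with 100% of values whole within a tolerance of 1e-06, and the reciprocal of the step (1.04 and 0.985 for HET0016, 1.02 and 0.981 for NC) equalled the median-ratio size factor recomputed over the 4 libraries. The whole reads recovered in this way came to 18259789 and 17276241 in the HET0016 libraries and to 17249097 and 17455456 in the NC libraries. Genes detected numbered 23593 and 23806 with HET0016 and 24324 and 23854 in NC. The deposited gene length column was annotation and was not used.

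Because the deposited unit is not raw counts, the main test was limma-trend (limma 3.58.1, R 4.3.3, with trended and robust variance) on log2(value + 1), as fixed before the data were examined. Genes needed a value of at least 1 in at least 2 libraries, which left 24027 genes. P-values were adjusted with the Benjamini-Hochberg method and called at 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of genes with few reads. For such genes the ratio of summed reads per group is given with its exact 95% binomial interval, and where a group had no reads only the limit of that interval is given. These intervals cover counting error only.

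The genes named were fixed by a rule before the data were examined. It took the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap and whose mean value was at least 1, up to 4 members of smallest p of each gene list, and all measured CYP4 omega-hydroxylases. In addition, the 16 genes of smallest p were taken after their values were seen. Some genes that these rules took are not reported here. The 36 gene lists were also written beforehand, and the 35 with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry.

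GC content and length were taken from the longest coding transcript of each gene in GENCODE 29, or the longest transcript where none codes; 11 tested genes had no value. A correction added after the data were seen fitted, in each library, the deviation from the gene mean as smooth functions of GC content and log2 transcript length (mgcv 1.9.3) over genes with a mean value of at least 20, and subtracted it. Near-identical copies of the named genes were sought with blastn 2.17.0 at 95% identity over at least 100 bases. Genes with such copies, or overlapping another gene, are uncertain because the counting of shared reads is not known.

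Settings listed before the data were examined were median centring, quantile normalization, no filter, a stricter filter of 5, pseudocounts of 0.1 and 5, the replicate number as a block, leaving out each library, and other thresholds. Alternatives added later were edgeR 4.0.16 (quasi-likelihood test, with and without the block), DESeq2 1.42.0 and limma-voom on the recovered reads, and the GC and length correction, also with each library left out and with an estimated correlation for the lists. Levels in rpm are recovered reads of a gene scaled to a common total of reads in genes. No library pair was a duplicate: over genes with at least 20 reads, the chi-square per degree of freedom was 6.95 between the HET0016 libraries and 3.61 between the NC libraries.

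The main test was tested on simulated data, drawn for this comparison of 2 against 2 libraries with 24001 genes tested and 200 genes changed. The changed genes were drawn from those with a mean value of at least 20. It recovered 35 of 67 genes changed by 1.5-fold, 55 of 67 changed by 2-fold and 65 of 66 changed by 4-fold, with 11 false calls, and made 0 calls when no gene was changed. The simulated genes varied independently, each by the spread usual at its expression, and libraries of a group did not differ by GC content. The real HET0016 libraries did, so these counts do not give the false calls or the recovery in the real data. When a GC trend was added to the simulated libraries, 2908 unchanged genes were called without the correction and 7 with it, which recovered 153 of the 200 changed genes. A simulated shifted list gave a camera p of 8.8e-51 and an unshifted one 0.398. Their genes were independent, so this does not show how camera behaves with correlated genes.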

Results

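RNA-seq profiles were collected from cells labelled MDA-MB-231 after exposure to HET0016, an inhibitor of 20-HETE synthesis, at 5 µM for 48 h (2 libraries) and from the NC cells (2 libraries). The libraries held 18259789 and 17276241 reads in genes with HET0016 and 17249097 and 17455456 in NC. Protein-coding genes took 96.4% to 96.6% of these reads. Values below are normalised read counts, given as mean ± SD over n = 2 libraries.

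The comparison asks which transcripts differ between cells exposed to HET0016 and NC cells. Of the genes of smallest p, chosen after their values were seen, most were lower with HET0016, while SPCS2P4, KIF21A and TPR, given below, were higher. IGFBP6, which codes for an insulin-like growth factor binding protein, fell from 4598 ± 604 in NC to 1892 ± 227 (log2 fold change -1.28 ± 0.09 SE, limma adjusted p = 2.7e-38). VSIR, which codes for the immune checkpoint protein VISTA, fell from 1163 ± 32.2 to 423 ± 50.9 (-1.46 ± 0.11, adjusted p = 2.1e-34). DHRS3, a retinal reductase, fell from 204 ± 8.74 to 39.4 ± 6.94 (-2.35 ± 0.23, adjusted p = 7.4e-22). LTBP3, a binding protein of latent TGF-beta, fell from 7126 ± 96.2 to 4322 ± 351 (-0.72 ± 0.09, adjusted p = 1.3e-12), and ELF3, an epithelial transcription factor, fell from 4025 ± 253 to 2491 ± 261 (-0.69 ± 0.09, adjusted p = 2.1e-10).

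In both HET0016 libraries these 5 genes lay below both NC libraries. IGFBP6 lies on chromosome 12 (53097436 to 53102345), VSIR on chromosome 10 (71747559 to 71773498) and DHRS3 on chromosome 1 (12567910 to 12617731). LTBP3 lies on chromosome 11 (65538805 to 65558930) and ELF3 on chromosome 1 (202007945 to 202017188). No copy with 95% identity was found for any of the 5, while 18.5% of the exonic bases of ELF3 lie opposite its antisense gene ELF3-AS1. After the correction for GC content and length their log2 fold changes were -0.97 ± 0.07 for IGFBP6, -1.29 ± 0.09 for VSIR, -2.17 ± 0.21 for DHRS3, -0.51 ± 0.06 for LTBP3 and -0.57 ± 0.07 for ELF3, with adjusted p of 8.9e-08 or less each.

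**Figure D1:**
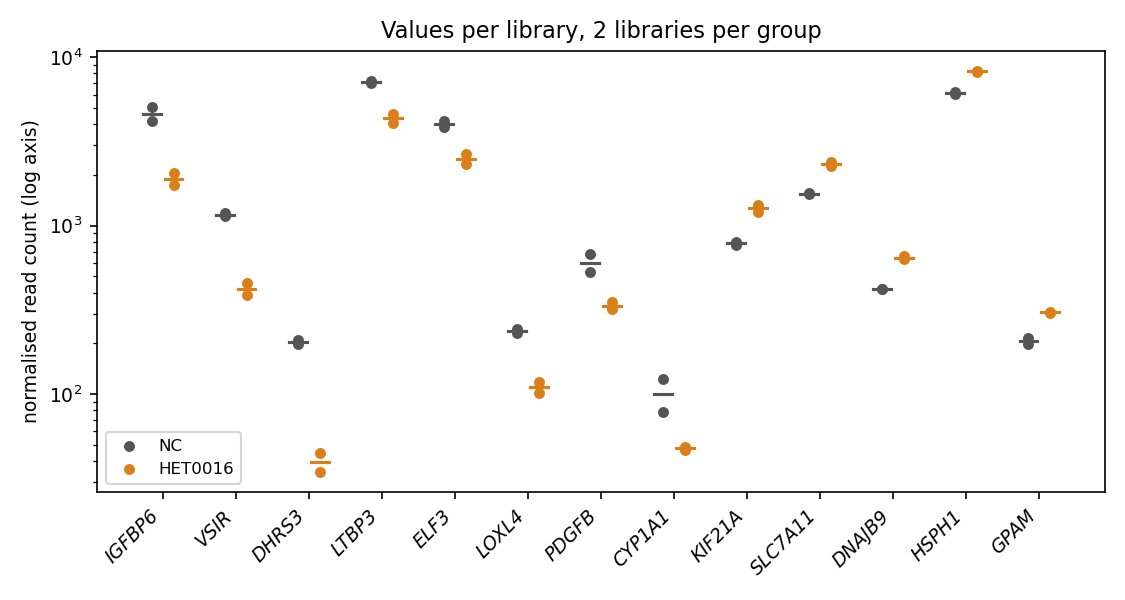
Normalised read counts (log axis) of 13 named genes in each library, with points for libraries and bars for the mean of the 2 libraries per group. For IGFBP6 the NC libraries sit at 4171 and 5025 and the HET0016 libraries at 2053 and 1732; for KIF21A the NC libraries sit at 765 and 802 and the HET0016 libraries at 1212 and 1333.

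Of 24027 genes tested, 1469 were higher and 713 lower with HET0016 at an adjusted p under 0.05, and 5294 had an unadjusted p under 0.05. Most differences were small: 114 of the higher and 183 of the lower genes changed by at least 1.5-fold. The share of calls that were higher was 67.3%, and it was 54.5% after median centring (1276 higher, 1067 lower) and 53.2% after quantile normalization (1119 higher, 986 lower). On the recovered whole reads, edgeR called 1742 genes higher and 837 lower among 15831 tested.

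The calls followed the GC content of the transcripts. Genes called higher had a median GC content of 39.9%, genes called lower 59.7%, and the other genes with a mean value of at least 20 had 50.3%. Across 13768 genes, which are not independent replicates, the log2 fold change ran against GC content with a Spearman rho of -0.69. For HET0016 replicate 1 alone against NC rho was -0.55 and for replicate 2 alone -0.72. A trend of the same sign and smaller span lay between the HET0016 libraries (rho -0.48 for replicate 2 against replicate 1), while rho was -0.10 between the NC libraries. After a per-library correction for GC content and transcript length, chosen after seeing the data, 133 genes were higher and 195 lower, and 205 of these 328 were among the calls of the main test. Of the 144 named genes past the threshold, 52 also passed after the correction. Without HET0016 replicate 2 the main test called 21 genes, against 1062 without HET0016 replicate 1, 261 without NC replicate 1 and 655 without NC replicate 2.

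**Figure D2:**
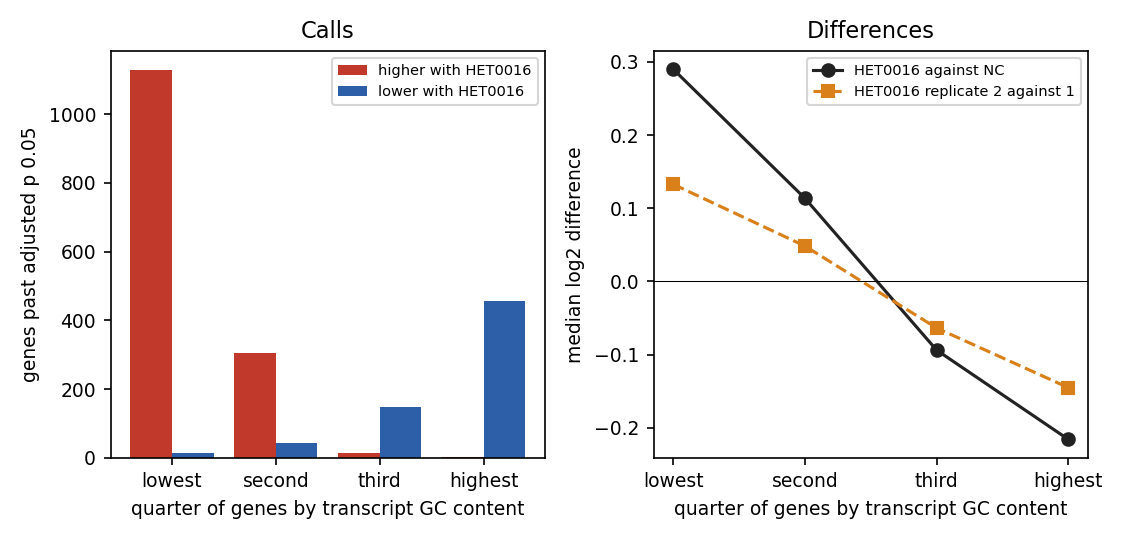
Left, numbers of genes past an adjusted p of 0.05 in each of 4 bins of 3442 genes by transcript GC content, higher (red) and lower (blue) with HET0016; right, median log2 difference per bin, HET0016 against NC (circles) and HET0016 replicate 2 against replicate 1 (squares). In the bin of lowest GC content 1128 genes were higher and 14 lower, and in the bin of highest GC content 2 were higher and 457 lower.

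**Figure D3:**
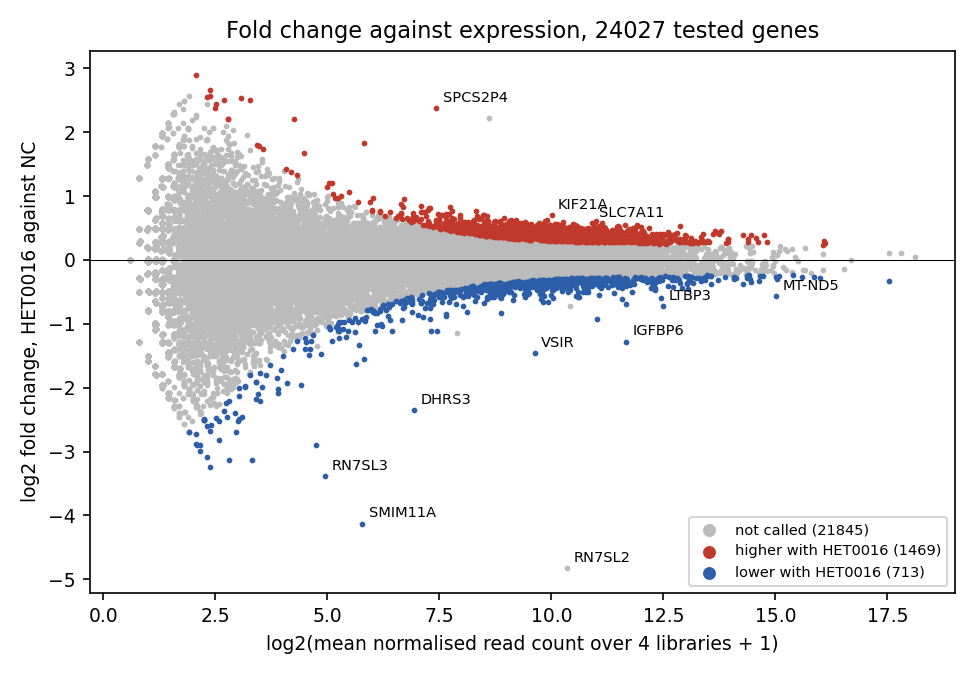
Log2 fold change of each tested gene (HET0016 against NC) against the log2 of its mean normalised read count plus 1, with genes called higher in red (1469), lower in blue (713) and not called in grey. VSIR at -1.46, IGFBP6 at -1.28 and DHRS3 at -2.35 lie apart from the genes of like expression, while RN7SL2 at -4.83 was not called (adjusted p = 0.101).

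The largest falls and rises by fold change, taken by the rule, were mostly genes with few reads. SMIM11A, a small membrane protein gene on chromosome 21 (34375480 to 34407866), fell from 103 ± 10.0 to 5.38 ± 3.30 (log2 fold change -4.13 ± 0.39, limma adjusted p = 4.8e-22). Its transcript is 100% identical to its copy SMIM11B, which had values from 0 to 1.93, so its level is uncertain. RN7SL3, a gene of the 7SL RNA of the signal recognition particle, fell from 54.8 ± 19.1 to 5.02 ± 4.38 (-3.39 ± 0.46, adjusted p = 7.2e-10), and RN7SL5P and RN7SL4P had 16 and 14 reads in NC and 0 with HET0016 (upper 95% limits of the ratio 0.253 and 0.294). Copies cover 100%, 73.5% and 80.0% of these 3 transcripts. GOLGA2P7 fell from 45.7 ± 21.4 to 6.32 ± 6.06, with copies over 69.2% of its transcript. FXYD3, a regulator of the sodium pump that shares 40.7% of its exonic bases with AC020907.6, had 17 reads in NC and 0 with HET0016 (upper limit 0.237). ADAMTSL4-AS1, with 28.1% of its exonic bases opposite ADAMTSL4, had 14 reads in NC and 0 with HET0016 (upper limit 0.294), and FAM242C, whose whole transcript lies in copies, and AC010307.2 each had 13 and 0 (upper limit 0.320). AC024940.3 (1 read with HET0016, ratio 0.0425, 95% interval 0.00103 to 0.261), FLJ13224, antisense to SINHCAF (3 reads, ratio 0.0888, 0.0174 to 0.283) and AC139495.3 (1 read, ratio 0.0514, 0.00124 to 0.323) were the other falls. The last has copies over 100% of its transcript.

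Among the largest rises, SPCS2P4, a processed pseudogene 99.1% identical to SPCS2, rose from 50.7 ± 10.5 to 293 ± 177 (log2 fold change 2.38 ± 0.21, limma adjusted p = 2.5e-23), with 174 and 412 reads in the HET0016 libraries; after the GC and length correction its adjusted p was 0.136. DNAH7, an axonemal dynein heavy chain gene, rose on 31 reads against 4 (ratio 7.57, 95% interval 2.68 to 29.5). FYB2 rose on 27 reads against 3 (8.79, 2.70 to 45.3) and the lincRNA LINC00920 on 21 against 3 (6.84, 2.04 to 35.8). ENTPD3 and the transporter gene ABCG4 each rose on 17 reads against 2 (8.30, 1.97 to 74.1), CCDC181 on 20 against 2 (9.77, 2.37 to 86.2), MAMDC2 on 15 against 1 (14.6, 2.25 to 617), and LINC01988 and MTND4LP14 each on 16 against 1 (15.6, 2.43 to 655). The antisense gene TNKS2-AS1 had 13 reads with HET0016 and 0 in NC (lower 95% limit of the ratio 2.98), and AC138866.2, whose whole transcript lies in copies, had 61 against 11 (5.42, 2.82 to 11.4). Of the 24 genes in these sets of extremes, edgeR on the recovered reads called 9 and the GC-corrected test 7. Most of those that edgeR did not call were not tested by it: its filter on reads left 149 of the 168 named genes, and 1 of these lost its call. The falls that lost the call with the correction still lay between -2.54 (RN7SL4P, -2.89 before) and -2.85 (AC010307.2, -2.88 before). A lost call alone thus does not show that a change went with GC content.

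Other genes of smallest p, chosen after their values were seen, were KIF21A, a kinesin motor gene, which rose from 784 ± 26.4 to 1272 ± 85.8 (log2 fold change 0.70 ± 0.11, limma adjusted p = 7.9e-08), and TPR, a nuclear pore protein gene, which rose from 1608 ± 98.8 to 2478 ± 485 (0.61 ± 0.10, adjusted p = 5.0e-07). Both passed after the GC and length correction (adjusted p = 2.7e-04 and 0.0102).

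Of the CYP4 omega-hydroxylases, the enzyme family that HET0016 inhibits, 3 genes had enough signal to test and 0 passed, also when adjusted over the list alone. CYP4V2 had 333 ± 43.0 with HET0016 and 268 ± 21.9 in NC (log2 fold change 0.31, limma adjusted p = 0.164), CYP4F3 had 19.8 ± 0.674 and 26.1 ± 3.52 (-0.38, adjusted p = 0.655) and CYP4F12 had 0.964 ± 1.36 and 3.55 ± 3.63 (-1.13, adjusted p = 0.513). CYP4F3 shares 46.3% of its transcript with CYP4F2 and is uncertain. Of 25 genes of arachidonic acid metabolism, 2 rose, 1 fell and 22 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.822). ACSL4, which activates arachidonic acid, rose (0.40), as did the efflux transporter ABCC4 (0.49), and the lipoxygenase ALOX15 fell from 9.04 ± 3.07 to 0.964 ± 1.36 (-2.52, adjusted p = 0.0278). None of the 3 passed after the GC and length correction, though ALOX15 kept most of its fall (-2.40, limma adjusted p = 0.151). Of 25 genes of ion channels and vascular 20-HETE signalling, 1 rose (TRPM7, 0.51) and 0 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.922).

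Camera with its preset correlation called 5 of 35 lists, 3 lower and 2 higher with HET0016. With an estimated correlation none was called (camera adjusted p = 0.945 for each of the 5). Fry called none in its test of 1 direction and 15 in its test of change in either direction. Camera with an estimated correlation rests on the few residual degrees of freedom of 4 libraries, so hardly any list could pass, here and below. After the GC and length correction the estimated correlation of the YAP and TEAD list was -0.0073, under the preset 0.01, yet that list lost its call. Such a loss does not show correlated genes and does not decide for or against a list. Of 26 YAP and TEAD targets, 0 rose, 6 fell and 20 did not pass (1 rose and 7 fell when adjusted over the list alone; camera adjusted p = 0.0034). AMOTL2, an angiomotin-family gene of the Hippo pathway, fell from 3725 ± 10.2 to 2426 ± 34.8 (-0.62 ± 0.09), AJUBA fell (-0.46), and so did the phosphatase gene PTPN14 (-0.37) and the matricellular CTGF (-0.39). After the GC and length correction 4 list members were lower and the list passed (camera adjusted p = 6.1e-05; adjusted p = 0.866 with an estimated correlation). Without NC replicate 2 its camera adjusted p was 0.0633.

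Of 22 unfolded protein response genes, 6 rose, 1 fell and 15 did not pass (9 rose and 2 fell when adjusted over the list alone; camera adjusted p = 0.0123). DNAJB9, an endoplasmic reticulum co-chaperone, rose from 420 ± 1.93 to 644 ± 18.3 (0.62 ± 0.12), HSP90B1 rose (0.41), and so did DNAJC3 (0.43) and the calnexin gene CANX (0.39). Of 22 heat shock and chaperone genes, 7 rose, 1 fell and 14 did not pass (8 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.0108). HSPH1 rose from 6127 ± 141 to 8228 ± 96.2 (0.43 ± 0.09), and HSP90AA1 (0.39), HSPD1 (0.39) and DNAJB4 (0.48) rose. HSP90AA1 and HSPD1 have pseudogene copies over 62.6% and 70.1% of their transcripts. After the GC and length correction 3 genes of the first list and 2 of the second were higher and 0 lower, and both lists passed (camera adjusted p = 2.2e-04 and 2.5e-06; adjusted p = 0.866 with an estimated correlation for each). Of the genes named, DNAJB9, HSP90B1, HSP90AA1 and HSPD1 passed after the correction, while DNAJC3 (0.15), CANX (0.16), HSPH1 (0.15, adjusted p = 0.314) and DNAJB4 (0.16, adjusted p = 0.556) did not. Without HET0016 replicate 1 their camera adjusted p was 0.217 and 0.637, and without NC replicate 2 it was 0.0633 and 0.0859.

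Of 41 nuclear genes of oxidative phosphorylation, 0 rose, 3 fell and 38 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.0033). The cytochrome c oxidase subunit genes COX6A1 (-0.58) and COX8A (-0.56) fell, and so did NDUFA1 of complex I (-0.32); COX6A1 has a copy over 57.7% of its transcript. After the GC and length correction 5 were lower, COX6A1 but not COX8A or NDUFA1 among them, and the list passed (camera adjusted p = 0.0011; adjusted p = 0.866 with an estimated correlation). Of 51 ribosomal protein genes, 0 rose, 7 fell and 44 did not pass (11 fell when adjusted over the list alone; camera adjusted p = 0.0028). RPLP1 (-0.34), RPL8 (-0.33), RPL35 (-0.31) and RPS9 (-0.28) fell. After the correction 2 were higher and 5 lower, of those named RPLP1 alone, and the list did not pass (camera adjusted p = 0.495). Without NC replicate 2 neither list passed (camera adjusted p = 0.176 and 0.197).

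Of 15 mitochondrially encoded genes, 3 rose, 2 fell and 10 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.724). MT-ND5 fell from 39587 ± 4809 to 26705 ± 3057 (-0.57 ± 0.08, limma adjusted p = 1.8e-09) and MT-ND6, the one protein gene of the list on the opposite strand, fell from 6760 ± 47.2 to 4488 ± 216 (-0.59 ± 0.09, adjusted p = 5.5e-08). The 2 genes are neighbours on the mitochondrial genome (12337 to 14148 and 14149 to 14673). The kit does not mark strand, so reads of the 2 strands cannot be told apart there and the 2 falls may not be independent. MT-ND4 rose from 62605 ± 1974 to 76608 ± 2150 (0.29 ± 0.08) and MT-CO2 rose (0.27). These 4 genes also passed after the GC and length correction, MT-ND5 at -0.65 and MT-ND6 at -0.67. MT-CO2, MT-ND4 and MT-ND6 have nuclear copies over nearly their whole length.

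**Figure D4:**
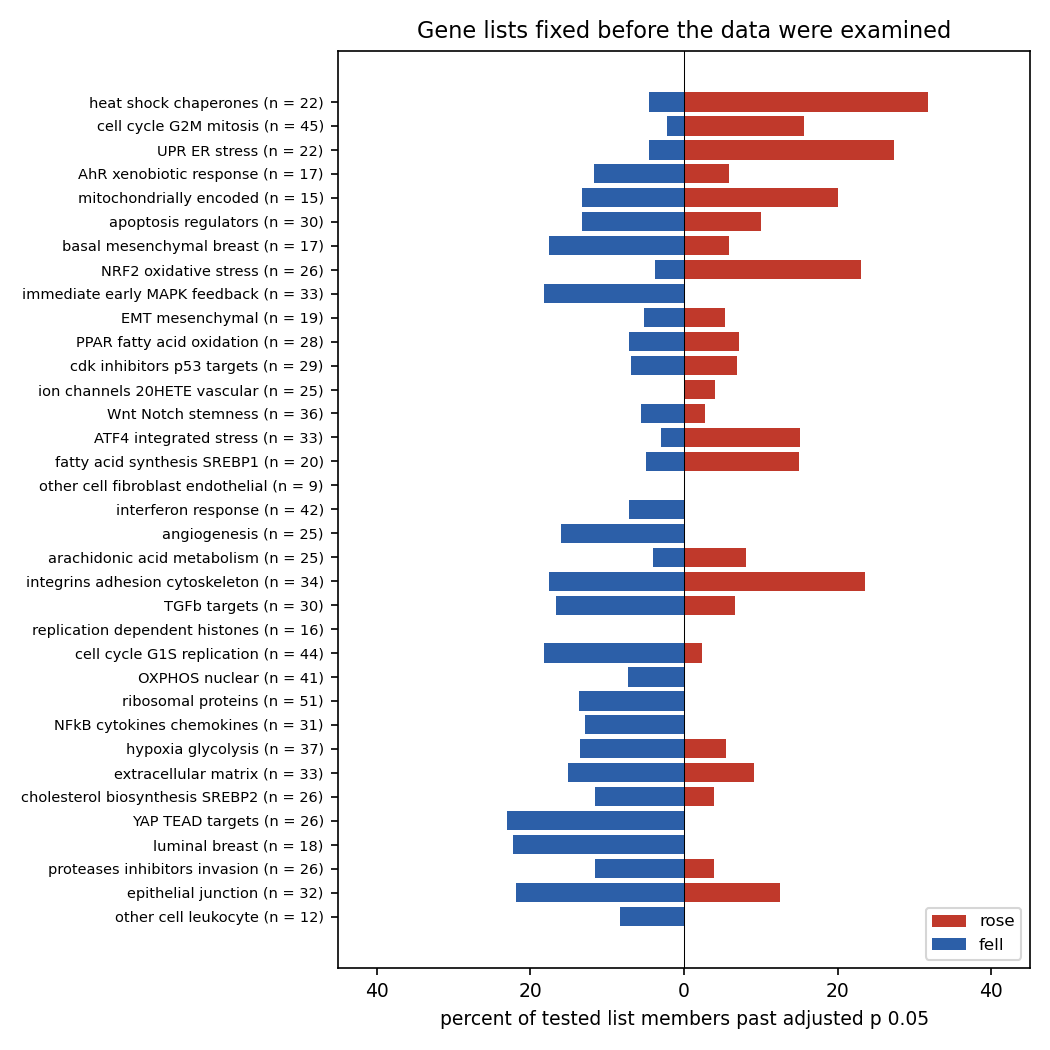
Percent of the tested members of each gene list past an adjusted p of 0.05, with rises to the right (red) and falls to the left (blue), and the number tested in brackets. Heat shock chaperones had 7 rises and 1 fall of 22, and YAP and TEAD targets 0 rises and 6 falls of 26.

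The remaining lists did not pass camera. Of 33 genes of the ATF4 integrated stress response, 5 rose and 1 fell (6 and 2 when adjusted over the list alone; camera adjusted p = 0.708). SLC7A11, the cystine transporter, rose from 1550 ± 17.0 to 2319 ± 92.0 (0.58 ± 0.10, limma adjusted p = 2.6e-06), and CEBPG (0.37), MTHFD2 (0.30) and GARS (0.29) rose. After the GC and length correction 3 were higher and the list passed (camera adjusted p = 7.3e-06), but not with an estimated correlation (adjusted p = 0.866). Of the genes named, GARS passed, while SLC7A11 (0.24, adjusted p = 0.0822), CEBPG and MTHFD2 did not. Of 26 NRF2 and oxidative stress genes, 6 rose and 1 fell (7 and 2 when adjusted over the list alone; camera adjusted p = 0.365), among them NFE2L2 itself (0.38), GCLM (0.42) and, lower, GPX2 (-0.42). Corrected for GC content and length, 2 of them were higher and 2 lower. Of 17 aryl hydrocarbon receptor and xenobiotic genes, 1 rose and 2 fell (3 and 4 when adjusted over the list alone; camera adjusted p = 0.938). CYP1A1 fell from 100 ± 31.0 to 47.5 ± 1.74 (-1.03 ± 0.25, limma adjusted p = 0.0021), ALDH3A1 fell (-0.51) and ABCC2 rose (0.31); CYP1A1 also passed after the correction (adjusted p = 0.0344).

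Of 25 angiogenesis genes, 0 rose and 4 fell (2 rose and 6 fell when adjusted over the list alone; camera adjusted p = 0.177). PDGFB, a platelet-derived growth factor gene, fell from 603 ± 107 to 335 ± 21.4 (-0.83 ± 0.12, limma adjusted p = 5.0e-08), and NRP2 (-0.38), THBS1 (-0.37) and CYR61 (-0.38) fell. Of 33 extracellular matrix genes, 3 rose and 5 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.177). LOXL4, a lysyl oxidase gene, fell from a mean of 237 to 110 (-1.11 ± 0.18, limma adjusted p = 6.3e-07), FBLN1 (-0.53) and the perlecan gene HSPG2 (-0.43) fell, and the laminin gene LAMA3 rose (0.37). Of 30 TGF-beta targets, 2 rose and 5 fell (3 and 6 when adjusted over the list alone; camera adjusted p = 0.083), with LTBP3, JUNB (-0.44) and ID1 (-0.36) lower and SNAI2 (0.42) higher. Of 26 proteases and inhibitors of invasion, 1 rose and 3 fell (1 and 5 when adjusted over the list alone; camera adjusted p = 0.101), with KLK6 (-0.43), MMP15 (-0.41) and CTSD (-0.35) lower and ADAM9 (0.29) higher. Under the correction 1 angiogenesis gene was higher and 3 lower, 2 matrix genes were higher and 2 lower, 1 TGF-beta target was higher and 3 lower, and 1 protease-list gene was higher and 0 lower.

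Of 32 epithelial junction genes, 4 rose and 7 fell (6 and 9 when adjusted over the list alone; camera adjusted p = 0.106). The keratin genes KRT8 (-0.33), KRT18 (-0.29) and KRT19 (-0.30) fell and the desmoplakin gene DSP rose (0.33). Of 34 integrin, adhesion and cytoskeleton genes, 8 rose and 6 fell (8 and 8 when adjusted over the list alone; camera adjusted p = 0.767), with ITGA2 (0.43), ITGA6 (0.38), CALD1 (0.43) and ROCK1 (0.50) higher. Of 19 mesenchymal genes, 1 rose (SNAI2) and 1 fell (S100A4, -0.37), with the same counts when adjusted over the list alone (camera adjusted p = 0.777). With the GC and length correction the junction list had 1 higher and 3 lower, the integrin list 0 higher and 1 lower, and the mesenchymal list 1 higher and 0 lower. The higher mesenchymal gene was then VIM (0.32, limma adjusted p = 0.0132), not SNAI2 (0.23, adjusted p = 0.285).

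Of 44 genes of G1/S and replication, 1 rose and 8 fell (2 and 8 when adjusted over the list alone; camera adjusted p = 0.117), with CCND3 (-0.48), CDT1 (-0.36), MCM2 (-0.35) and MCM7 (-0.32) lower. Of 45 mitotic genes, 7 rose and 1 fell (11 and 1 when adjusted over the list alone; camera adjusted p = 0.0603), with HMMR (0.52), ASPM (0.40), CENPF (0.34) and TOP2A (0.30) higher. Their median GC contents were 49.4% and 43.2%. Once GC content and length were corrected for, 0 replication genes were higher and 3 lower (camera adjusted p = 0.0023; adjusted p = 0.866 with an estimated correlation), and 0 mitotic genes were called (camera adjusted p = 0.758). Of 29 CDK inhibitor and p53 target genes, 2 rose and 2 fell (2 and 3 when adjusted over the list alone; camera adjusted p = 0.831), with CDKN1A (-0.37) and GADD45B (-0.42) lower and RRM2B (0.47) and CCNG1 (0.30) higher. Of 30 apoptosis regulators, 3 rose and 4 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.728). BCL2L1, an anti-apoptotic gene, fell from 9806 ± 457 to 7141 ± 313 (-0.46) with its antisense gene ABALON over 43.0% of its exons, and TNFRSF12A (-0.59) and BIK (-0.42) fell. After the correction 0 and 0 of the p53 list and 0 and 2 of the apoptosis list were higher and lower.

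Of 26 cholesterol synthesis genes, 1 rose and 3 fell (3 and 5 when adjusted over the list alone; camera adjusted p = 0.146), with FDPS (-0.34) and TM7SF2 (-0.37) lower. Of 20 fatty acid synthesis genes, 3 rose and 1 fell (4 and 3 when adjusted over the list alone; camera adjusted p = 0.767), with GPAM (0.57), ACSL3 (0.42) and ME1 (0.35) higher and FADS2 (-0.43) lower. Of 28 PPAR and fatty acid oxidation genes, 2 rose and 2 fell (3 and 3 when adjusted over the list alone; camera adjusted p = 0.785), with ETFDH (0.49) higher and PPARD (-0.50) and ACADVL (-0.32) lower. Of 37 hypoxia and glycolysis genes, 2 rose and 5 fell (2 and 7 when adjusted over the list alone; camera adjusted p = 0.117), with HIF1A (0.38) higher and SLC16A3 (-0.51), SLC2A3 (-0.44) and PKM (-0.27) lower. Under the correction the counts of higher and lower genes were 0 and 0 for cholesterol synthesis, 0 and 0 for fatty acid synthesis, 0 and 1 for fatty acid oxidation, and 0 and 3 for hypoxia.

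Of 31 NF-kappaB cytokine and chemokine genes, 0 rose and 4 fell (0 and 5 when adjusted over the list alone; camera adjusted p = 0.147). LIF, a cytokine of the interleukin-6 family, fell from 1052 ± 11.6 to 688 ± 81.1 (-0.62 ± 0.11, limma adjusted p = 9.4e-06), and TNFAIP2 (-0.68), CXCL1 (-0.58) and CXCL3 (-0.51) fell. With the GC and length correction 4 were lower and the list passed (camera adjusted p = 0.0274), but not with an estimated correlation (adjusted p = 0.910). Of 42 interferon response genes, 0 rose and 3 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.421): PSMB8 (-0.45), HLA-B (-0.36) and HLA-C (-0.33). Of 33 immediate early and MAPK feedback genes, 0 rose and 6 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.728), with JUNB, EPHA2 (-0.38), IER2 (-0.35) and ETV4 (-0.34) lower. Of 36 Wnt, Notch and stemness genes, 1 rose (BMI1, 0.42) and 2 fell (ALDH1A3, -0.46, and NKD2, -0.38), with the same counts when adjusted over the list alone (camera adjusted p = 0.938). After the correction 1 interferon gene was higher, 2 immediate early genes were higher, and 1 gene of the Wnt and Notch list was higher and 1 lower. Of 16 replication-dependent histone genes, 0 were called by limma (camera adjusted p = 0.728).

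Of the genes named for the lists that did not pass camera, other than GARS and the 4 mitochondrially encoded genes, those that also passed after the GC and length correction were NFE2L2, GPX2, CYP1A1, PDGFB, NRP2, THBS1, LOXL4, FBLN1, LAMA3, LTBP3, DSP, KRT8, ELF3, CCND3, BCL2L1, TNFRSF12A, SLC16A3, SLC2A3, LIF, TNFAIP2, CXCL1, CXCL3, ALDH1A3 and LYZ. Of the YAP and TEAD targets, AMOTL2, AJUBA, PTPN14 and CTGF passed. Reads of some named genes may be shared with others, and their values are uncertain. Copies cover 78.7% of the transcript of KRT17, 68.8% of KRT18, 79.8% of SLC2A3 and 76.9% of RPL35, and other genes overlap 52.7% of the exonic bases of CTSD, 44.5% of NDUFA1, 34.5% of COX8A, 34.0% of LYZ, 33.2% of MTHFD2 and 30.8% of IER2.

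In 7 lists the median, mean and camera direction differed in sign. These were arachidonic acid metabolism (median -0.07, mean -0.15, camera up), p53 targets (0.03, 0.00, down), fatty acid synthesis (-0.01, 0.04, up), fatty acid oxidation (0.04, -0.06, down), xenobiotic genes (0.13, -0.06, up), immediate early genes (0.06, -0.03, down) and Wnt and Notch genes (0.01, -0.02, down).

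Markers of breast cell types and of other cells are given in rpm, reads per gene scaled to a common total of reads in genes. Of the 17 basal and mesenchymal breast markers tested, 1 rose (ITGA6) and 3 fell (KRT17, -0.53, S100A2, -0.51, and GSTP1, -0.27), with 1 and 4 when adjusted over the list alone; of 18 luminal markers 0 rose and 4 fell (KRT8, KRT18, KRT19 and TFF3, -0.31), with 2 and 5 when adjusted over the list alone. Camera adjusted p was 0.885 and 0.341. Corrected for GC content and length, 1 basal marker was higher and 0 lower, and 0 luminal markers were higher and 1 lower. The basal marker was then VIM (0.32, limma adjusted p = 0.0132), not ITGA6 (0.17, adjusted p = 0.201), and the luminal marker was KRT8. Of 12 leukocyte markers 1 fell (LYZ, from 84.4 ± 11.2 to 47.7 ± 11.5, -0.82, limma adjusted p = 0.0244) and of 9 fibroblast and endothelial markers 0 were called by limma, with the same counts when adjusted over the list alone (camera adjusted p = 0.158 and 0.728). No leukocyte marker exceeded 20 rpm in both NC libraries (0 of 22), and no fibroblast or endothelial marker did (0 of 18). VIM, the vimentin gene, a marker of mesenchymal lines such as MDA-MB-231, had 86.1 and 81.2 rpm in NC and 94.7 and 92.7 with HET0016, and the epithelial KRT8 had 11614 and 12513 in NC and 9966 and 9063 with HET0016. CDKN2A, a gene known to be deleted in MDA-MB-231, had 248 and 253 rpm in NC and 227 and 193 with HET0016.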

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

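The tests with edgeR, DESeq2 and limma-voom and all with the GC and length correction were chosen after the data were seen. The 5 genes IGFBP6, VSIR, DHRS3, LTBP3 and ELF3 were lower with HET0016 in 20 of 20 settings and past the threshold together in 16. DESeq2 is not among the 16 because it gave DHRS3 (log2 fold change -2.37) no adjusted p, while it called IGFBP6, VSIR, LTBP3 and ELF3. Of the 168 named genes, median centring kept 161, no filter 164, a pseudocount of 5 164 and quantile normalization 156 in direction and on the same side of the threshold; a pseudocount of 0.1 kept 118, the stricter filter 148 of 162 and the replicate block 24, and leaving out HET0016 replicate 1 kept 100 of 164, HET0016 replicate 2 37 of 165, NC replicate 1 65 of 161 and NC replicate 2 74 of 160. DESeq2 kept 104 of 119, edgeR 145 of 149 and limma-voom 145 of 149 that it tested. The GC and length correction kept 74, ended the call of 91 and turned the sign of 3: HIST1H1C to 0.0295, GSTP1 to 0.0400 and LUM to -0.10. The median of the ATF4 list turned to -0.13 without HET0016 replicate 1 and was 0.11 without HET0016 replicate 2. The cause was not tested for these 4 values.

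Against 2182 genes called, 1469 higher, 713 lower and 297 changed by at least 1.5-fold, a pseudocount of 0.1 gave 1094, 811, 283 and 142, and the GC and length correction gave 328, 133, 195 and 57. DESeq2 called 455 genes lower and 57 changed by at least 1.5-fold. An adjusted p under 0.01 left 1009 genes and a fold of at least 2 left 117. Leaving out 1 library gave 21 to 1062 genes in all, 4 to 723 higher, 17 to 339 lower and 21 to 283 changed by at least 1.5-fold (21 without HET0016 replicate 2 and 150 without NC replicate 1). These fits assume that the lone library of a group varies like the other group. With the correction, leaving out HET0016 replicate 1 or replicate 2 gave 0 genes in every count, beside 1301 and 1253 with an unadjusted p under 0.05; without NC replicate 1 it gave 177 (44 higher, 133 lower, 49 by at least 1.5-fold) and without NC replicate 2 187 (94 higher, 93 lower, 44 by at least 1.5-fold). Fewer libraries leave fewer degrees of freedom; beyond that, the cause was not tested.

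Taking the replicate number as a block gave 1 gene (0 higher, 1 lower, 1 by at least 1.5-fold), beside 4386 with an unadjusted p under 0.05. Replicates of like number shared no more than the number (r = 0.0252 across 13772 genes), and the block left 1 residual degree of freedom. With the block in edgeR the calls were 2019 higher and 1018 lower.

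Of the 24 largest rises and falls, the stricter filter kept 11, a pseudocount of 0.1 kept 7, the block 0, edgeR 9, edgeR with the block 10, limma-voom 9 and the correction 7; leaving out 1 library kept 3 to 9, and with the correction 0, 0, 2 and 3. DESeq2 gave no adjusted p for these 24. Fewer of these genes, with few reads, are tested under the stricter filter and by edgeR and limma-voom, which had their own filter on reads. Otherwise the cause was not tested. Of the 5 lists called, 0 were called with an estimated correlation, with or without the GC and length correction, and 0 by fry in 1 direction, and leaving out 1 library gave 0 to 10 lists. The test with an estimated correlation could hardly call any list with 4 libraries, as given above. With 2 libraries per group, 35 of 67 simulated 1.5-fold changes were recovered, among independent genes with a mean value of at least 20.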

Other observations

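The tests chosen only after their result was seen are the calls left without HET0016 replicate 2 and the median of the 5 genes IGFBP6, VSIR, DHRS3, LTBP3 and ELF3. Genes called in the main test, under median centring, quantile normalization, both other pseudocounts and the stricter filter, with the GC and length correction, and by edgeR and DESeq2 numbered 75 higher and 58 lower with HET0016. DHRS3 was not counted, since DESeq2 gave it no adjusted p. The genes named next were chosen from the 75 higher and 58 lower genes after their values were seen. No list made up of genes of their kinds was tested, so they stand as single genes, each with its log2 fold change before and after the GC and length correction. Some were members of other lists tested here, such as GARS of the ATF4 list and TGM2 of the retinoic acid-induced genes. Of genes coding for aminoacyl-tRNA synthetases, TARS rose from 10775 to 14339 (0.41, 0.23), EPRS from 3838 to 5403 (0.49, 0.29), NARS from 2963 to 3906 (0.40, 0.26) and GARS from 6378 to 7819 (0.29, 0.28). NCL, which codes for nucleolin, rose (0.33, 0.26), as did NOP58 of the box C/D particles (0.47, 0.28) and the GTPase genes GNL2 (0.46, 0.36) and GNL3 (0.45, 0.31). The initiation factor genes EIF3A (0.45, 0.25) and EIF2S2 (0.35, 0.24) and the poly(A)-binding PABPC1 (0.28, 0.31) rose.

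Among the lower ones, AKR1B1, the aldose reductase gene, fell from 1184 to 748 (-0.66, -0.51), the annexin genes ANXA6 (-0.54, -0.38) and ANXA11 (-0.46, -0.43) fell, and the neighbours TMEM176A (-0.66, -0.37) and TMEM176B (-0.63, -0.38) fell. APOBEC3G, a cytidine deaminase gene, fell from 354 to 203 (-0.81, -0.76), A2M, which codes for a protease inhibitor, fell (-0.65, -0.69), and GNE, the first enzyme of sialic acid synthesis, fell from 1889 to 1260 (-0.59, -0.74). TGM2, a transglutaminase gene, fell from 1044 to 735 (-0.52, -0.41).

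The number of calls moved with GC content and with 1 library. After the GC and length correction 328 genes were called, against 2182 before it. The correction takes out any difference that follows GC content or length, technical or biological, so this drop cannot tell the 2 apart. The log2 fold change also ran with transcript length (Spearman rho 0.30). Median length was 5047 bases for genes called higher and 2323 for genes called lower. GC-dependent recovery of fragments remains a candidate explanation of most small changes. Without HET0016 replicate 2 the calls were 21, which a deviating library could give, but 261 were left without NC replicate 1, and the GC trend was present in HET0016 replicate 1 alone (rho -0.55 against NC), so it does not lie in replicate 2 only. The fall of IGFBP6, VSIR, DHRS3, LTBP3 and ELF3 went in part with that trend: their median log2 fold change was -1.28 before and -0.97 after its removal, and all 5 still passed. The trend as fitted thus does not hold their whole fall. Genes and test were chosen after their values were seen, so this cannot settle the cause. With the correction and either HET0016 library left out, they lay between -0.49 (LTBP3) and -2.30 (DHRS3). A response to HET0016 remains a candidate explanation for these 5 genes, which 2 libraries per group without stated cultures cannot separate from a difference between cultures.

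The 7SL RNA genes held 2342 and 3278 reads in NC and 275 and 303 with HET0016, over 102 genes, and RN7SL2 alone had values of 1973 and 3060 against 60.7 and 121 (log2 fold change -4.83, limma adjusted p = 0.101). A different split of reads among the copies does not account for this, since the log2 ratio of their summed rpm was -3.31. A lower yield of all short RNAs without a poly(A) tail would lower other such genes alike. The 7 with a mean value of at least 20 had a median of 0.24 (95% interval -0.08 to 0.28). Single genes ran from -0.94 (SNORD3B-1) to 1.01 (SNORD99). SNORD3A, SNORD3B-1 and SNORD3B-2 are of the same family, so the interval is too narrow. Even the lowest lay well above -3.31, which argues against an equal loss in these genes, though they are few and had low values. A loss of 7SL RNA alone in preparing the libraries was not tested. No biological explanation was tested.

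Some, not all, transcripts of intestinal epithelium were abundant in the libraries labelled MDA-MB-231: in NC, NKD1 had 5928 and 6235 rpm, VIL1 276 and 277, CDX2 47.3 and 48.8 and LGR5 85.3 and 91.9, beside a median of 14.6 for protein-coding genes, while FABP1 had 3.71 and 3.04, LGALS4 2.32 and 1.37, CEACAM5 0.522 and 0.229 and KRT20 0 and 0.0573. MTAP and CDKN2B, which lie with CDKN2A in the segment deleted in MDA-MB-231, had 62.8 and 65.6, and 57.6 and 51.0, while FN1 had 11.6 and 9.80. Of 24 further intestinal markers 17 exceeded 5 rpm in both NC libraries (not, for example, GPA33, GUCY2C and PHGR1). With MTAP above 5 rpm, this met the limit set before the count for RNA mostly from an intestinal-like line. That limit is low: EGFR at 4.99 rpm in NC replicate 1 ranked at percentile 35.7 of protein-coding genes, so most such genes pass. Of 18 further transcripts abundant in MDA-MB-231, 10 exceeded 20 rpm, which met the limit for a mixture with MDA-MB-231 cells. At the same 20 rpm 14 of the 24 intestinal markers passed, and AXL at 20.4 rpm in NC replicate 1 ranked at percentile 55.7. The counts thus do not tell these explanations apart, and both stay possible. Others of these 18 go against a large share of such cells: in NC, SRGN had 0.290 and 0.687 rpm, NNMT 0.870 and 0.344, GLIPR1 1.45 and 0.573 and CD74 1.62 and 1.26, and IL6 and FSTL1 are not listed; the mixture stays open, since levels in pure MDA-MB-231 cells were not used here, and no biological explanation was tested.

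Because DHRS3 and RARB (mean 26.1 in NC, log2 fold change -1.93, limma adjusted p = 0.0046) respond to retinoic acid, it was tested whether 18 other retinoic acid-induced genes were lower as a class. Their median was -0.23 with a camera p of 0.0263. With an estimated correlation the camera p was 0.138, though that version could hardly call any list here. After the GC and length correction the median was -0.07 and the camera p 0.0973, so a lower retinoic acid response may be present but is not shown. Among them RARG (-0.51), TGM2 and STRA6 (-0.33) fell and NRIP1 rose (0.45); of these 4, TGM2 alone passed after the correction.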
